A study of Bos taurus with 30 samples.

How the data were processed

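Small RNA was sequenced from the testes of 30 Holstein-Friesian bull calves, 15 on a High and 15 on a Moderate plane of nutrition, with 1 library per calf. Per the labels' protocols, total RNA was extracted with the Qiagen RNeasy Plus Universal kit and libraries were made with the Illumina TruSeq small RNA kit. Per the submitters' processing notes, the tools used were FastQC 0.11.8, cutadapt 2.6, R 3.4 and edgeR 3.5. The aligner, the miRNA reference and the genome build are not given in the sources used here.

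The authors deposited 1 table for the whole series, with 1030 bovine miRNAs in rows and 1 column per library. Although its name speaks of counts, the deposited values are a normalized signal: each column holds CPM computed with a library size scaled by the trimmed mean of M values (TMM), the default scaling of edgeR. This was worked out from the values. The low values of each column are multiples of what 1 read is worth, and dividing by that step gave whole reads for 95.3% of the 18379 values above 0, within a tolerance of 0.02 read (94.0% to 96.8% per library). TMM factors computed from these recovered reads differed from those implied by the deposited sums by at most 0.000212 on the natural log scale. The other values are fractions of a read and belong to 58 miRNAs. The way these reads were divided is not given in the sources used here, so miRNAs with several gene copies or near-identical family members are uncertain (miR-124a and miR-124b hold the same values in every library, as do miR-129 and miR-129-5p; all 4 were kept). Of the 1030 miRNAs, 192 were listed at 0 in all libraries and 838 were above 0 in at least 1.

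The diet of each library was taken from the diet characteristic in its label, which has the same diet as the ending of the sample code for all 30 libraries. The columns of the deposited table carry that sample code. The sample titles give the other diet for 18 of the 30 libraries: 9 libraries of the High diet are titled Moderate and 9 of the Moderate diet are titled High. The labels do not say which is right. All results were therefore computed by the diet characteristic, and the comparison was repeated with the diet in the titles and in the 12 libraries (6 per diet) in which both labels give the same diet. Replicate numbers follow accession order and pair no libraries.

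Since the values are not counts, the main test was limma 3.58.1 with a mean-variance trend on log2(value + 0.5), with diet as the only term. It covered the 387 miRNAs with a value of at least 1 in at least 15 libraries, which held at least 99.988% of the reads of each library. P-values are two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2(value + 0.5) scale, which understates changes of low miRNAs, and are High minus Moderate. The edgeR quasi-likelihood test that had been planned before the data were examined needs counts and was run on the recovered reads as an alternative (edgeR 4.0.16), as was DESeq2 1.42.0. Fixed before the data were examined were also the 23 miRNA lists (families, genomic clusters and cell-type markers), matched on the miRNA number without arm. The 15 lists with at least 3 tested members were tested with camera (preset correlation 0.01, and again with the correlation estimated per list) and with fry, both in limma. Mean list levels per library were compared by permutation with 100000 resamples. Overall profiles were compared by PERMANOVA (vegan 2.7.1, 9999 permutations) on log2(value + 2) and by principal components. Analyses used R 4.3.3, with sva 3.50.0 for surrogate variables.

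The miRNAs named in the text follow a rule fixed before the data were examined: all miRNAs past the threshold if there are 25 or fewer, the 10 with the highest mean value, and in each list up to 3 tested members with the smallest p. Any other miRNA named was chosen after its values were seen, and the text says so. The position of miRNA genes relative to each other was taken from the RefSeq gene table of the assembly ARS-UCD2.0, in which 382 of the 387 tested miRNAs had a gene. Its coordinates are not printed, because the build used by the authors is not named in the sources used here.

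The recovered reads summed to 6.0003 to 19.98 megareads per library. A count of 0, with an upper limit of 3 reads, allowed 0.138 to 1.43 deposited units, depending on the library. This limit covers counting error only, since the reads carry no molecular identifiers. No pair of libraries agreed within sampling noise: over the 435 pairs the lowest chi-square per degree of freedom was 76.6. The tests were run on simulated data with known changes, 4 sets of 15 against 15 libraries drawn with the real means and depths. Apart from the changes, all simulated libraries shared 1 composition and miRNAs varied independently. None therefore stood apart as Moderate replicate 5 does in the real data, and the rates below hold for that simpler setting. limma recovered 45.6% of the miRNAs changed by 1.25-fold, 69.1% of those changed by 1.5-fold and 95.3% of those changed by 2-fold, and called 6 of 1370 unchanged miRNAs. camera found 10 of 10 simulated lists shifted by -0.3 on the log2 scale and called 0 of 200 unshifted lists, in data simulated without correlation between miRNAs.

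The alternatives covered other scalings, filters, pseudocounts, tools, covariates, depth ranges and the omission of each library in turn. Those chosen before the data were examined were the other scalings (including library totals alone), the filters, DESeq2, limma-voom with quality weights, the robust edgeR fit, the threshold of 0.1, both other groupings by label, the title diet or log10 depth as a covariate, 1 surrogate variable and rows of the same mature miRNA summed, and for the lists the estimated correlation, the title diet and library totals alone. The others, among them the omission of Moderate replicate 5, were added after seeing the data.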

Results

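The study asked whether the plane of nutrition in early life changes the miRNAs of the calf testis. From 2 to 12 weeks of age, calves of the High diet received 1.5 kg of milk replacer in 10 L per day with concentrate offered ad libitum, for an intended gain of 1.0 kg per day. Calves of the Moderate diet received 0.5 kg of milk replacer in 4 L and 0.5 kg of concentrate per day, for an intended gain of 0.5 kg per day. miRNAs, short RNAs that lower the translation and stability of the mRNAs they pair with, were measured by small RNA sequencing in 15 calves of each diet. Depth ranged from 6.0003 to 19.98 megareads (M reads). It fell into 2 ranges, with 24 libraries (11 High, 13 Moderate) at up to 10.3 M reads and 6 libraries (4 High, 2 Moderate) at 16.7 M reads or more. Values below are the deposited values in TMM-scaled CPM, that is, reads relative to a normalized library size, given as mean ± SD, and miRNA names are those of the file without the prefix bta. Diet is the diet characteristic. The titles give the other diet for 18 of the 30 libraries, so every statement about diet depends on that characteristic being the right label.

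The testis libraries were dominated by miR-10b, an miRNA encoded within a HOX gene cluster, which took 44.6% of the reads on average over the 30 libraries. miR-143, abundant in smooth muscle, took 11.7%, followed by miR-148a (5.37%), miR-26a (4.58%), miR-92a (2.47%), miR-181a (2.44%), miR-27b (2.30%), let-7f (1.69%), miR-127 (1.64%) and miR-191 (1.64%). Of these 10, miR-27b and miR-127 changed with diet. The other 8 did not pass the test, with log2 fold changes from -0.34 for miR-10b (95% confidence interval -0.76 to 0.07) to 0.07 for miR-92a (-0.02 to 0.16). One of them, miR-191, passed without Moderate replicate 5 (0.18, adjusted p = 0.0159 in limma; 0.00 with it), and miR-10b then stood at -0.14 (adjusted p = 0.192). A value above 0 was found for 622 ± 30.2 miRNAs in the High libraries and 603 ± 41.8 in the Moderate ones (permutation p = 0.160, n = 15 per diet, two-sided). Total reads were 10.9 ± 5.13 and 9.61 ± 3.90 M reads (permutation p = 0.476). The share of reads taken by the 10 most abundant miRNAs was 77.2% ± 1.66 under High and 79.7% ± 4.72 under Moderate, and the miR-10b share was 42.2% ± 2.87 and 47.0% ± 10.9. The permutation p-values of these shares were 0.0251 and 0.0343, and both became 0.0685 after adjustment over the 4 library measures. With Moderate replicate 5 left out, the Moderate shares were 78.6% ± 1.95 and 44.3% ± 3.14, and the unadjusted p-values 0.0503 and 0.0699.

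Moderate replicate 5 stood apart from all other libraries. miR-10b took 84.8% of its reads, against 37.0% to 49.0% in the other 29, and 476 miRNAs had a value above 0 in it, against 579 to 682. Its depth of 8.88 M reads lay within the range of the others, but miR-10b left fewer of these reads for the other miRNAs. Of the 387 miRNAs tested, 190 lay more than 3 SD from the mean of the other 29 libraries. miR-34c, at 9.51, and miR-33a, listed at 0 against 12.8 ± 2.48 in the other 29, were among the lowest (miR-33a was chosen after its values were seen). The first principal component, with 32.7% of the variance, set this library against the rest. For this reason the comparisons were repeated without it.

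The High diet was accompanied by higher levels of the miR-34 family and lower levels of miRNAs of the imprinted DLK1-DIO3 region. On the log2 scale, miR-34c rose 1.95-fold, from 64.6 ± 37.0 under Moderate to 113 ± 42.1 under High, and miR-34b rose 1.66-fold, from 4.74 ± 2.66 to 7.65 ± 2.74. Both come from 1 transcript that is abundant in meiotic and later male germ cells, and whether these testes held such cells was not tested. miR-34a, a p53-induced miRNA with the same seed, rose 1.40-fold, from 18.3 ± 3.13 to 26.7 ± 9.48. miR-127, the most abundant miRNA of the imprinted region, fell from 18348 ± 3215 to 14367 ± 2034, a log2 fold change of -0.35 with a standard error of 0.08. All 15 High libraries lay above the Moderate median for miR-34c and miR-34b, and all 15 lay below it for miR-127. The log2 fold change of miR-34c was 0.96, and 0.79 without Moderate replicate 5.

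In all, 19 of 387 miRNAs passed an adjusted p of 0.05 in limma, 9 higher and 10 lower under High. Besides the miR-34 miRNAs, those higher were miR-2419-5p (log2 fold change 0.78), miR-11995 (0.57), miR-497 (0.40), miR-22-3p (0.30), miR-425-5p (0.24) and miR-27b (0.23). miR-497 belongs to the miR-15/16 family, which targets cell cycle genes, and miR-27b has been linked to lipid metabolism. miR-22-3p was one of the more abundant, at 12517 ± 2051 against 10149 ± 1403. The lower ones outside the imprinted region were miR-483 (-0.45), which lies in an intron of the imprinted growth factor gene IGF2, and miR-320a (-0.21). miR-483 fell from 13.97 ± 4.10 to 9.84 ± 2.02, and all 15 High libraries lay below the Moderate median. The effects were modest. The 9 rises measured 17.7% to 94.8% and the 10 falls 13.7% to 29.7%, with adjusted p between 0.0260 and 0.0462. At an unadjusted p under 0.05 there were 82 miRNAs, where 19.4 are due to chance with no effect. With upper-quartile scaling 13 miRNAs were higher and 8 lower, and with library totals alone, which shifted the median log2 fold change by 0.20, none passed.

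**Figure D1:**
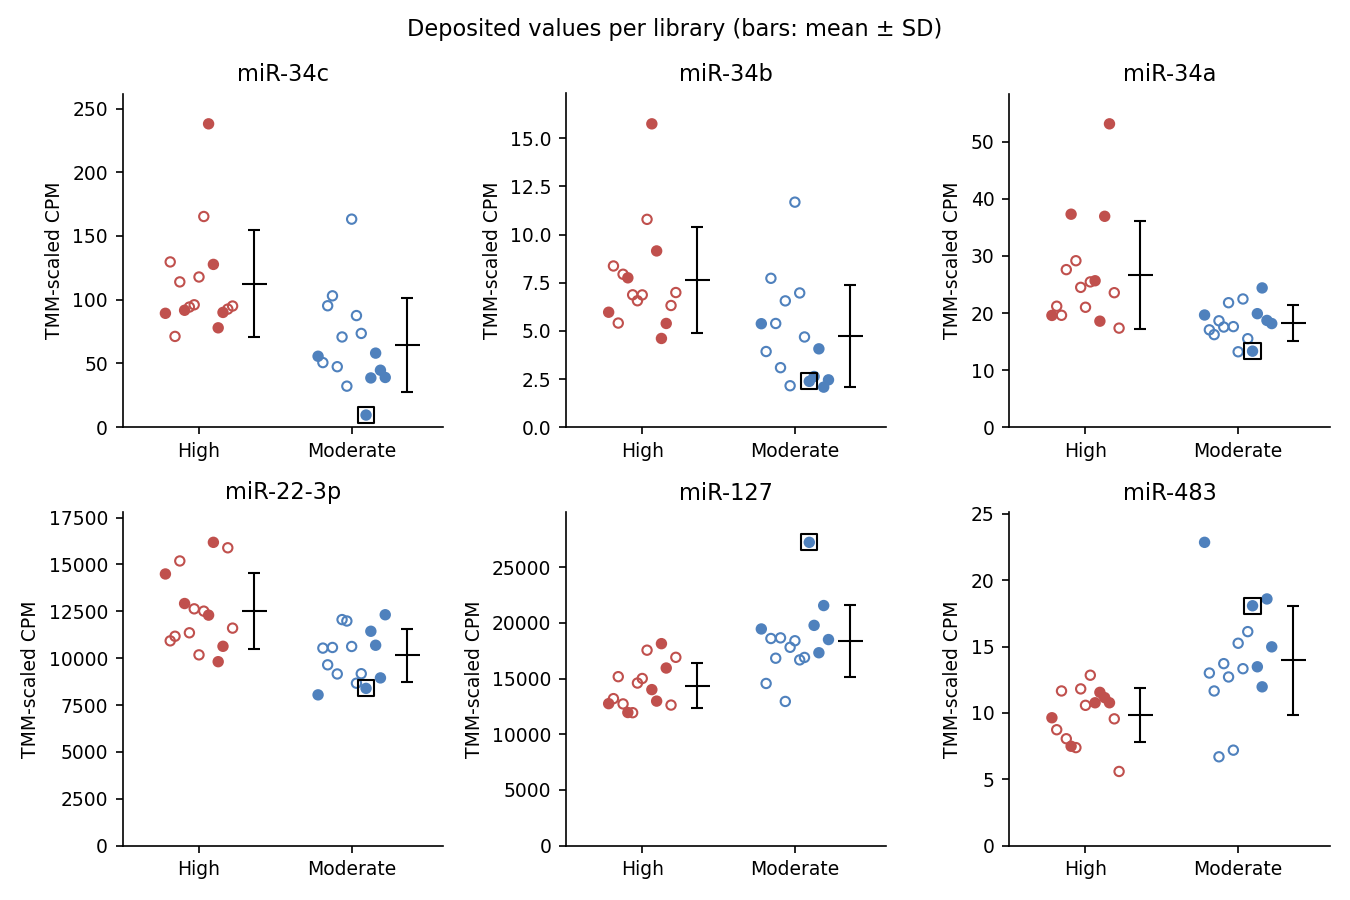
Deposited values (TMM-scaled CPM, linear axes from 0) of 6 miRNAs past the threshold, 1 point per library, by diet (15 libraries each), with mean ± SD as bars. Filled points are libraries whose title gives the same diet, open points those whose title gives the other, and the square marks Moderate replicate 5. miR-34c, miR-34b, miR-34a and miR-22-3p were higher under High and miR-127 and miR-483 lower, with overlapping ranges.

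The number of miRNAs past the threshold depended on single libraries. Without Moderate replicate 5, 45 of 385 passed, 19 higher and 26 lower, and all 19 of the full comparison were among them. Without High replicate 5 none passed: the lowest adjusted p was 0.0520, all 19 had an adjusted p under 0.1, and 75 miRNAs had an unadjusted p under 0.05. When each of the 30 libraries was left out in turn, miR-34c, miR-34a, miR-11995, miR-22-3p, miR-425-5p, miR-127, miR-376d, miR-3956 and miR-410 passed in 29 of the 30 fits and miR-34b in 24. The others passed less often, from 16 fits for miR-320a to 8 for miR-483 and 7 for miR-497. On the recovered reads of all 30 libraries, edgeR called 30 of 377 (9 higher, 21 lower; 17 shared with limma, miR-34b and miR-2419-5p standing at adjusted p of 0.0552 and 0.0504) and DESeq2 48 (20 higher, 28 lower), all 19 included.

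The DLK1-DIO3 region carries a large cluster of mammalian miRNAs, expressed from the maternal chromosome. Of the 46 tested members of this list, 8 fell, 0 rose and 38 did not pass in limma, while 16 fell and 0 rose in edgeR. Adjusted over the list alone, 21 fell. Adjusted over all miRNAs tested, 22 fell without Moderate replicate 5. The mean log2 fold change was -0.22 and the median -0.25, and 42 of the 46 were negative. With library totals alone the mean was -0.033, while the median of all tested miRNAs stood at 0.21. With library totals alone and without Moderate replicate 5, the mean was -0.18 and that median 0.07. Besides miR-127, the members that fell were miR-3956 (-0.51), miR-376d (-0.39), miR-432 (-0.39), miR-381 (-0.38), miR-411c-3p (-0.35), miR-410 (-0.28) and miR-487b (-0.27). miR-410, for instance, was at 593 ± 81.2 under High and 717 ± 94.2 under Moderate. Of the 10 miRNAs lower under High, 8 thus came from this region, and of the 26 lower ones without Moderate replicate 5, 22 did. The gene table placed 59 miRNA genes between DLK1 and DIO3, and of the 48 tested miRNAs from them 44 had a negative log2 fold change.

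**Figure D2:**
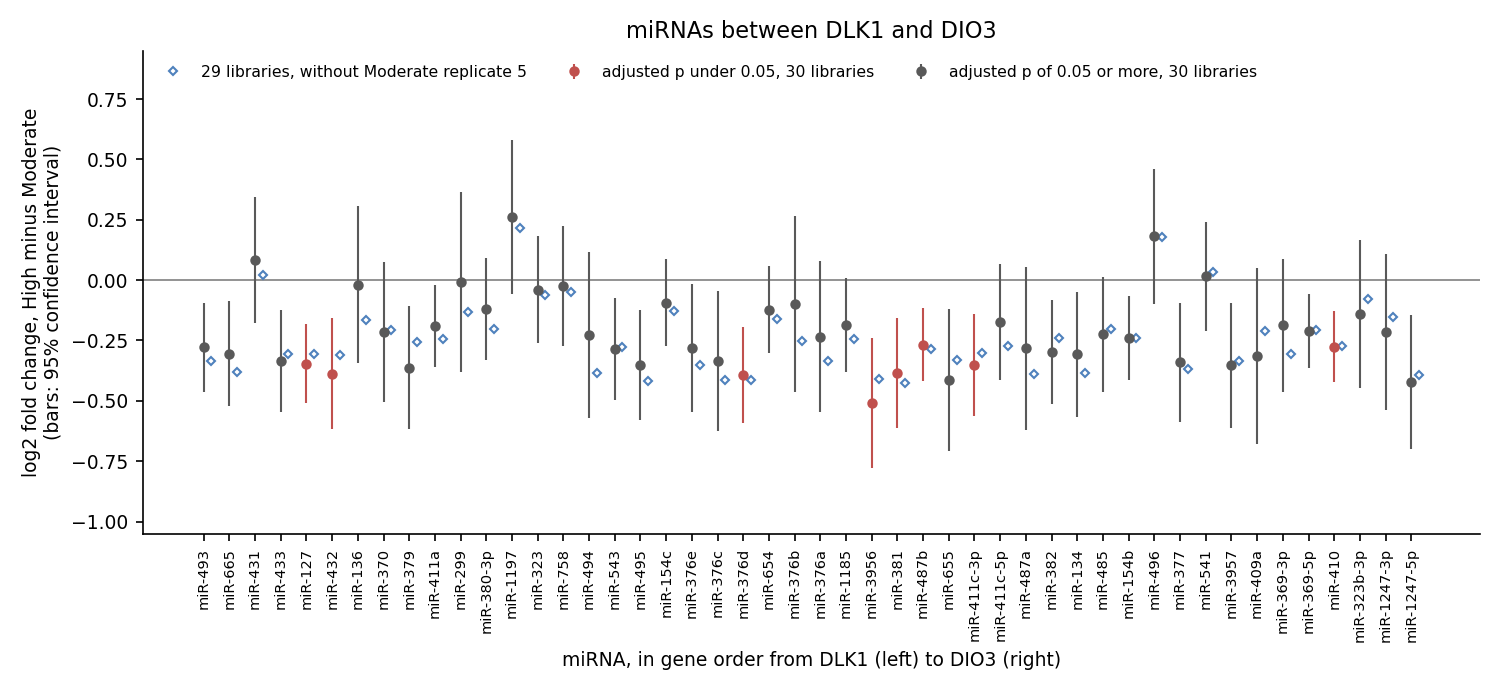
Log2 fold change (High minus Moderate, vertical axis, limma on log2(value + 0.5)) of the 48 tested miRNAs with a gene between DLK1 and DIO3, in gene order (horizontal axis, not to scale). Circles and bars are estimates and 95% confidence intervals from 30 libraries, red where the adjusted p is under 0.05, and diamonds are estimates without Moderate replicate 5. In the 30 libraries 44 of the 48 lie below 0, and the 8 past the threshold are spread along the region.

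This list was the 1 of 15 that camera called (adjusted p = 2.62e-16 with the preset correlation, adjusted p = 0.0544 with an estimated correlation of 0.253), and fry gave an adjusted p of 0.0232. Without Moderate replicate 5, camera with an estimated correlation gave an adjusted p of 0.0888 and fry one of 0.00243. Because members of a list vary together, the mean log2 level of the list was also compared per library, a test chosen after seeing the data. It was 4.19 ± 0.15 under High and 4.41 ± 0.18 under Moderate (n = 15 each, permutation p = 0.00180, two-sided; 0.0171 adjusted over 15 lists), and 13 of 15 High libraries lay below the Moderate median. Taken relative to the median of the other tested miRNAs in the same library, which a scaling factor hardly moves, the difference was -0.35 (standard error 0.06), larger than that of the list itself because the median of the others was higher under High, with all 15 High libraries below the Moderate median (permutation p = 1e-05, the smallest that 100000 resamples can give). Within the libraries under 12 M reads the difference in mean level was -0.25 (11 against 13, permutation p = 0.00207). In the 6 deeper libraries it was -0.11 (4 against 2, exact permutation p = 0.533).

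camera called no other list. In the list of miR-34b/c and the miR-449 family, which shares their seed, 2 of 3 tested members rose and miR-449a did not pass (log2 fold change 0.02, 95% confidence interval -0.33 to 0.38). camera gave this list an adjusted p of 0.105 and fry 0.0632, and the permutation test of its mean level, 0.57 higher under High, gave 0.00404 (0.0202 adjusted). Of 11 miRNAs linked to steroidogenesis, miR-34a rose and 10 did not pass (mean 0.11, camera adjusted p = 0.409, adjusted permutation p = 0.0171), with miR-212 at 0.36 and miR-138 at 0.33. Of 17 miRNAs linked to lipid, glucose and growth regulation, miR-27b rose and 16 did not pass (mean 0.11, and 0.05 without Moderate replicate 5; camera adjusted p = 0.113, fry 0.128), and fry passed without that library (0.0129) while camera did not (0.0986). Adjusted over this list alone 4 rose. Adjusted over all miRNAs tested, 3 rose without Moderate replicate 5: miR-27b, miR-29a and miR-29c. miR-29c, which represses collagen genes, stood at 0.39 (adjusted p = 0.0619 in limma, 0.0238 in edgeR and 0.00424 in DESeq2) in 30 libraries and at 0.28 (0.00645 in limma) in 29. miR-483 was the 1 tested member of the IGF2-H19 list. No member passed among 10 spermatogonia-associated miRNAs (mean 0.01, and -0.02 without Moderate replicate 5; camera pointed down), 4 associated with Sertoli and other gonadal somatic cells (0.05, and -0.02 without that library), 10 of the let-7 family (0.02, and 0.03), 15 of miR-17~92 and its paralogs (0.08, and 0.00), 7 of the miR-30 family (0.11, and 0.02) or 42 of the multi-copy miR-2284 and miR-2285 family of ruminants (mean 0.00, and -0.02; median -0.02). Their camera adjusted p lay between 0.393 and 0.987. The X-linked miR-507b stood at 0.48 (adjusted p = 0.0638 in limma, 0.0552 in edgeR and 0.0329 in DESeq2), miR-182 at -0.03 and miR-183 at -0.01, and the hypoxia-induced miR-210 at 0.19.

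Of the markers of other cell types, none passed in limma in the 30 libraries, and the striated muscle miRNA miR-499 passed in edgeR and DESeq2. The smooth muscle miRNAs miR-143 and miR-145 had log2 fold changes of -0.11 (95% confidence interval -0.32 to 0.09) and -0.15 (-0.43 to 0.12), and both arms of the endothelial miR-126 stood at 0.06 and 0.03. The 3 red blood cell miRNAs averaged 0.28 (camera adjusted p = 0.409), led by miR-144 (0.42). The 4 tested epithelial miRNAs averaged -0.25 (adjusted p = 0.113), with miR-200a at -0.33, miR-200b at -0.27 and miR-429 at -0.26. The 7 leukocyte miRNAs had a mean of 0.01 (0.02 without Moderate replicate 5) and a median of -0.06, with camera pointing down (adjusted p = 0.393). Of these, miR-146b was at 1146 ± 864 under High and 662 ± 709 under Moderate (log2 fold change 0.91, adjusted p = 0.145) and passed without Moderate replicate 5 (1.09, adjusted p = 0.0358). The 3 striated muscle miRNAs averaged 0.27 (adjusted p = 0.393; mean 0.14 without Moderate replicate 5), and miR-499 passed without Moderate replicate 5 (0.41, adjusted p = 0.0127; 0.57 and 0.0638 with it, where edgeR gave 0.0331 and DESeq2 0.00769). The 5 neural miRNAs averaged -0.02 (adjusted p = 0.954; mean 0.00 without Moderate replicate 5), with miR-124a and miR-124b, which hold the same values, counted as 2. With library totals alone, the mean of each of the 15 lists was above 0 except those of the DLK1-DIO3 and epithelial lists. The liver miRNA miR-122 and the clusters of miR-302, miR-367 and miR-371 had no tested member.

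Over the whole profile of 387 miRNAs, diet accounted for 7.52% of the variance (PERMANOVA permutation p = 0.0002), and for 9.62% without Moderate replicate 5 (permutation p = 0.0001, the smallest these permutations can give). On the second principal component, with 10.8% of the variance, the diets differed in mean (permutation p = 9.00e-05, 0.000450 adjusted over 5 components), with overlapping ranges. Without Moderate replicate 5 they differed in mean on the first, with 15.96% (permutation p = 7.00e-05, 0.000350 adjusted), again with overlap.

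With the diet given in the titles, none of the 387 miRNAs tested in limma passed (11 at an unadjusted p under 0.05), nor any of 377 in edgeR (15) or of 838 in DESeq2 (18). The title diet accounted for 2.98% of the variance of the profile (PERMANOVA permutation p = 0.771). In the 12 libraries whose labels give the same diet, none of 391 passed in limma (43 at an unadjusted p under 0.05; 69 of 390 without Moderate replicate 5) and none of 379 in edgeR (54), while 3 of 791 passed in DESeq2. All 19 miRNAs of the full comparison had the same sign there, although these 12 libraries are part of it. miR-34c and miR-34b had log2 fold changes of 1.602 and 1.18 in the 12. The mean level of the DLK1-DIO3 list differed by -0.21 in the 12 libraries (6 against 6, exact permutation p = 0.0909; -0.29 with 6 against 5, exact permutation p = 0.0152, without Moderate replicate 5) and by -0.22 in the 18 whose labels conflict, grouped by the diet characteristic (9 against 9, exact permutation p = 0.00987). The mean level of miR-34b and miR-34c differed by 1.39 in the 12 (exact permutation p = 0.00216). Without Moderate replicate 5 it differed by 1.18 there (6 against 5, exact permutation p = 0.00433). In the 18 it differed by 0.48 (exact permutation p = 0.0664), and the gap between the 12 and the 18 was not tested. Both this pair and the DLK1-DIO3 list were singled out in the full comparison, which holds the 12 and the 18. Their p-values in these parts are therefore not separate evidence. In the 18, none passed in limma and 59 had an unadjusted p under 0.05.

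**Figure D3:**
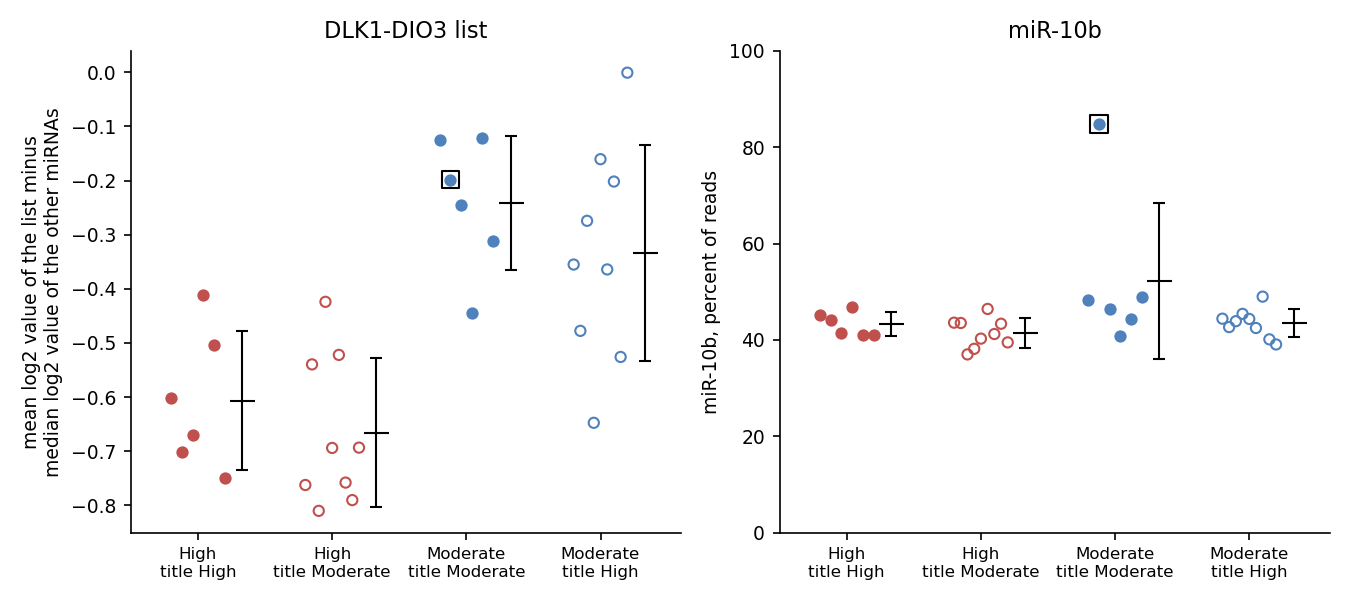
Left, mean log2 value of the 46 tested DLK1-DIO3 miRNAs minus the median log2 value of the other tested miRNAs. Right, miR-10b as a percent of reads. Each point is a library, grouped by diet characteristic and by the diet in its title (6, 9, 6 and 9 libraries), bars are mean ± SD, and the square marks Moderate replicate 5. The list is lower in both High groups, with means of -0.61 and -0.67, than in both Moderate groups, at -0.24 and -0.33, and Moderate replicate 5 has the highest miR-10b share, 84.8%.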

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

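Chosen after the result was seen were the tests on Moderate replicate 5 and on leaving it out, of the smooth muscle and endothelial miRNAs, of the list relative to the other miRNAs, of the list under median-of-ratios and upper-quartile scaling, with log10 depth and among the libraries under 12 M reads, and of the titles. Within the libraries grouped by diet and by whether both labels give the same diet (6 or 9 libraries each), 4 library measures made 16 sets of values, and 5 extreme values stood far from the rest of their set. For independent sets of normally distributed values, chance alone gives such a gap in about 1 of 20 sets. Depth fell into 2 ranges and the 4 measures come from the same libraries, so this rate is only a rough guide here. Among the 6 Moderate libraries whose labels match, Moderate replicate 9 had 18.6 M reads against at most 8.88 M reads in the other 5. Among the 9 Moderate libraries whose labels conflict, Moderate replicate 2 had 19.2 M reads against at most 10.3 M reads and 662 detected miRNAs against at most 625. These are the 2 Moderate libraries of the deeper range.

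The remaining values belong to Moderate replicate 5, in which the 10 most abundant miRNAs took 95.3% of the reads (at most 80.9% in the other 5 of its set) and miR-10b took 84.8% (at most 48.9%). Shallow sequencing is argued against by its total of 8.88 M reads, which lies within the 6.0003 to 19.98 M reads of the other 29. A different cell mix or another transcription would move both arms of a hairpin alike, since they are cut from 1 precursor, unless arm use itself changed. In this library the arms deviated in opposite directions in 12 of 32 hairpins, and in 1 of these by more than 1 (log2) each. Low arms rest on few reads here, and how much this adds to the spread was not tested. The difference between the 5p and 3p arms deviated from that of the other libraries with an SD of 1.72 (log2) over the 32 hairpins, against 0.194 to 0.391 in the other 29. This is consistent with sequence-dependent gain or loss during extraction or library preparation, which remains a hypothesis, since no miRNA sequences were used here and the base composition of the affected miRNAs was not tested.

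The lower DLK1-DIO3 list under High is the next pattern. Moderate replicate 5 is argued against as its cause by the mean log2 fold change of -0.24 without that library, and sequencing depth by -0.22 with log10 depth as a covariate and -0.25 among the libraries under 12 M reads. The authors' TMM scaling was set against 3 others. The change smallest in size was -0.033, with library totals alone, which moved the median of all miRNAs to 0.21. Without Moderate replicate 5, library totals alone gave -0.18 and a median of 0.07. Median-of-ratios scaling then gave -0.23 and upper-quartile scaling -0.22. Relative to the other miRNAs of each library, which a scaling factor hardly moves, the list stayed lower, by -0.35 with a standard error of 0.06. Of this, -0.22 is the change of the list itself and the rest a higher median of the other miRNAs under High. A lower share of smooth muscle and endothelial cells stays open: miR-143, miR-145 and miR-126 changed by 0.17 more than the list (standard error 0.09; 0.14 without Moderate replicate 5, standard error 0.09), and neither difference reaches 2 standard errors. That explanation could not be set aside, and it does not compete with the diet, since cell shares may themselves differ by diet. Whether the miRNAs of the list come from such cells was not tested. The diet is 1 of the open explanations, and the labels' conflict bears on it as well.

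The conflict of labels is the third pattern. Suppose the titles held the true diet and the diet caused the differences. The 18 libraries with conflicting labels would then show the opposite of the other 12 when grouped by the diet characteristic. The DLK1-DIO3 list cannot decide this, since it was singled out by its difference over all 30 libraries. Over all tested miRNAs, none of them singled out, the log2 fold changes of the 12 and the 18 libraries had a Pearson r of 0.443, where the titles would need a negative one. Of the 48620 groupings of the 18 into 9 and 9, a share of 0.00325 gave an r as large in size (r = 0.509 and a share of 0.00712 without Moderate replicate 5). This argues against the titles as the true diet of these 18, provided that the diet caused the differences. A factor other than the diet that goes with the sample code would also give a positive r. Why the titles differ is not given in the sources used here, and no biological explanation was tested.

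Other groupings of the libraries bear on whether chance can account for the number of calls. Of 100 splits of the 30 libraries into 15 and 15, the real one included, 1 gave as many as its 19 miRNAs, the real one itself, and the highest of the others gave 0. Without Moderate replicate 5, 1 of 100 splits gave as many as the real 45, again the real one, and the highest other gave 3. Chance is therefore unlikely for both counts but not excluded, since 100 splits cannot give a share below 1 in 100. The count of 45 also rests on leaving out a library after seeing the data. For the title diet (highest other 0) and for the 12 libraries whose labels match (highest other 1) the real count is 0, which all 100 splits reach by construction, so the splits say nothing about chance there. For the number of lists called by camera chance cannot be excluded: 73 of 100 splits gave at least the real count of 1, and the highest other gave 5, so that camera with its preset correlation calls lists too readily in these correlated data. The mean change of the DLK1-DIO3 list itself, at -0.22, was the largest in size of the 100 splits, with 0.18 as the highest other. The list had been singled out in these same libraries and was set only against its own values, so this is not separate evidence.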

How the results depend on the processing

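The alternatives that leave out libraries, by depth range, with filterByExpr, with other pseudocounts or with rows of the same values kept once were chosen after seeing the data, as were the list means under median-of-ratios or upper-quartile scaling or with log10 depth. edgeR on all libraries had been planned as the main test and became an alternative once the values proved to be normalized. The count of 19 kept within 1.5 times under median-of-ratios and upper-quartile scaling (21 each), at least 10 in 15 libraries (14), the title diet (22) or log10 depth (17) as a covariate, filterByExpr (19), pseudocounts of 0.1 (19) and 2 (21), and tested miRNAs with the same values in every library summed or kept once (19 each). It fell to 0 with library totals only (61 at an unadjusted p under 0.05), with no filter (104 of 838, more miRNAs tested), with the title diet (11) and in the 12 libraries whose labels match (43, fewer libraries), to 3 in the libraries under 12 M reads and to 2 in those over. It rose to 29 with robust edgeR, 30 with edgeR (9 higher, 21 lower), 47 with edgeR without Moderate replicate 5, 48 with DESeq2, 49 at an adjusted p under 0.1, 62 with limma-voom and quality weights and 62 with 1 surrogate variable. The surrogate variable stood at -0.956 in Moderate replicate 5 and between -0.0489 and 0.127 in the other libraries, so it mostly marked that library. Leaving out 1 library gave 0 to 45. Besides High replicate 5 (0) and Moderate replicate 5 (45), the count fell to 12 without High replicate 1, 11 without High replicate 8 or Moderate replicate 1 or 2, 10 without High replicate 4, 13 or 14 or Moderate replicate 4, 8 or 13, and 9 without High replicate 10 or Moderate replicate 6. The adjusted p of the 19 lay between 0.0260 and 0.0462. Over the 19 miRNAs and the alternatives other than leaving out 1 library, 307 of the resulting values kept direction and side of the threshold, 118 kept direction only and 7 reversed. The count of 45 without Moderate replicate 5 was steadier: 34 to 60 on leaving out 1 more library, 31 with library totals only (23 higher, 8 lower), with no filter or under 12 M reads, 47 with edgeR, 59 with DESeq2, and 0 with the title diet. In the 12 libraries DESeq2 called 3. The number of lists called was 0 with an estimated correlation, where the DLK1-DIO3 mean of -0.22 had an adjusted p of 0.0544, and 2 with library totals only, the epithelial list joining. With the title diet camera called 1 list, let-7 (mean -0.040, adjusted p = 0.0443), and not DLK1-DIO3 (mean 0.049, adjusted p = 0.263). With the title diet too, miR-376d was at 0.017, miR-11995 at -0.013, miR-3956 at 0.016, miR-410 at 0.081, miR-22-3p at -0.019 and miR-2419-5p at -0.33, all of opposite sign to the main values. In the libraries over 12 M reads miR-22-3p was at -0.014. The profile share was 2.98% with the title diet. The difference in the share of the 10 most abundant miRNAs, -2.49 percentage points, was -0.954 with the title diet and -1.37 without Moderate replicate 5, neither past an unadjusted p of 0.05. The cause was not tested except where stated. The tested miRNAs with the same values were 2 pairs, miR-129 with miR-129-5p and miR-124a with miR-124b. No paired analysis was possible because the replicate numbers follow accession order. At 6.0003 to 19.98 M reads, miRNAs near 1 deposited unit rest on few reads. The 451 miRNAs below the filter were not tested in the main comparison; with no filter and without Moderate replicate 5 none of them passed (lowest adjusted p 0.0727).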

Other observations

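The grouping by genomic neighbourhood and its tests were chosen after seeing the data. Tested miRNAs whose genes lie within 10 kb of each other formed 16 groups of 3 or more. Besides 2 groups of the DLK1-DIO3 region (38 members, mean difference -0.22; 7 members, -0.23; adjusted permutation p = 0.0148 for both), the group of miR-374a, miR-545-3p and miR-545-5p was higher under High by 0.31 on the log2 scale (permutation p = 0.000140, 0.00224 adjusted over 16 groups; 0.25 and 0.00245 without Moderate replicate 5), while camera gave an adjusted p of 0.149 (0.0287 without Moderate replicate 5). None of its members passed alone: miR-545-5p was at 8.58 ± 2.00 under High and 6.44 ± 1.76 under Moderate (0.42, adjusted p = 0.0820), miR-545-3p at 1.92 ± 0.55 and 1.37 ± 0.54 (0.41) and miR-374a at 93.4 ± 6.60 and 88.8 ± 19.9 (0.09, and 0.15 with an adjusted p of 0.0148 without Moderate replicate 5). Their genes lie on the X chromosome near XIST in mammals. The group of miR-296-3p, miR-296-5p and miR-6123 was higher by 0.19 (0.0154 adjusted; 0.11 and 0.0303 without Moderate replicate 5; camera adjusted p = 0.495), with miR-296-3p at 0.00 and miR-296-5p at 0.39. The other 12 groups had adjusted permutation p-values of 0.195 or more.

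Within the DLK1-DIO3 list, 4 members had a positive log2 fold change, miR-1197 (0.26), miR-496 (0.18), miR-431 (0.08) and miR-541 (0.02), with adjusted p of 0.353 or more. All miRNAs named here outside the rule were chosen after their values were seen. miR-1247-5p, from a gene between DLK1 and DIO3 that was not in the list, stood at -0.42 (adjusted p = 0.0638). Without Moderate replicate 5, miRNAs lower under High outside the region were miR-483, miR-320a, miR-199a-5p and miR-484. The 10 that then joined the 9 higher ones were miR-29a, miR-29c, miR-32, miR-146b, miR-191, miR-374a, miR-421, miR-499, miR-6120-3p and miR-6522, with log2 fold changes from 0.13 for miR-29a to 1.09 for miR-146b. All 26 lower and 19 higher miRNAs without that library rest on 15 High and 14 Moderate libraries.

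A hypothesis written down before its test was that higher miR-34b/c and lower DLK1-DIO3 levels lie on 1 axis of variation between calves, in which case they would correlate negatively within each diet. Within High, Pearson's r between the mean level of miR-34b/c and that of the list was -0.178 (n = 15, permutation p = 0.528) and Spearman's rho was -0.289 (p = 0.295). Within Moderate r was -0.00873 (n = 15, p = 0.9753) and rho -0.182 (p = 0.515), and without Moderate replicate 5 r was -0.481 (n = 14, p = 0.0824) and rho -0.455 (p = 0.105). Adjusted over these 3 relations, the lowest p was 0.247 for r and 0.315 for rho. After leaving out the 2 libraries farthest from the median miR-34b/c level, r was -0.543 in High, -0.534 in Moderate and -0.454 in Moderate without replicate 5. The signs go with the hypothesis and the permutation p-values do not pass, so with 15 calves per diet a shared axis may or may not exist.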
